A study of Pseudomonas fluorescens with 2 samples.

How the data were processed

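RNA-seq measured the transcriptome of *Pseudomonas fluorescens*, a soil and water bacterium, after 1 h in flowback water or in phosphate-buffered saline (PBS). Flowback water is the fluid that returns to the surface after hydraulic fracturing. Per the labels' protocols, wild-type cells were grown in LB at 25 °C to an OD600 near 0.3, and RNA from 3 independent experiments on different days was pooled before each library was made. Each library was built from 1 µg of RNA with a bacterial kit that includes removal of rRNA (ScriptSeq Complete). There was thus 1 library per condition. The pooling averages the 3 days, but it leaves no spread between replicates to measure.

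For each library the authors deposited RPKM values (read numbers scaled by feature length and by library depth) for 6106 features, per the file headers. The aligner, its settings and the reference assembly are not given in the sources used here. Features carry a gene symbol (1058 features, 1018 distinct symbols) or a PFLU locus tag alone (5048 features). By the convention of such tags, 16 were read as rRNA, 66 as tRNA and 15 as other small RNA features. Symbols carried by more than 1 feature are given with the start and end that the feature names hold; 76 names hold such a span, on the authors' reference. Locus tags were not translated into names. Strand, product descriptions and sequences were not used here, so gene lists were matched by symbol only and GC content was not examined.

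Whole reads were recovered from the RPKM values. A value equals reads divided by feature length and by library depth, so the ratio of the values of a feature in both libraries fixes the relative depth, and the 76 named spans fix the length scale. The length behind the values was end minus start: 47 of the 65 named spans detected in both libraries then gave a single depth, against 2 with end minus start plus 1. The RPKM denominators came out as 5417170 reads for flowback water and 5654229 reads for PBS. At the precision of the files (10 significant digits or 9 decimals) the smallest whole reads that explain both values were found for 4806 of 4806 features detected in either library. They are lower bounds, and so are the shares of reads taken from them. Their sums reached 95.3% of each denominator, and 55 of the 65 named spans came out at their named length.

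The spans are wider than genes. Neighbouring named spans overlapped in 7 of 7 pairs, by 486 to 599 bases, and the shortest recovered span was 603 bases, a pattern that about 300 bases added on each side would give. Reads near a gene end can then be credited to a neighbour. How the authors' counting divided such reads is not given in the sources used here, and the values of closely spaced genes are uncertain to that extent. Reads from opposite strands could not be told apart for overlapping features.

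The comparison was the log2 ratio of flowback water over PBS on the scale of log2(RPKM + 0.255). The pseudocount is the 5th percentile of the values above 0, and it understates differences of low genes. Ratios were taken for the 3397 features with a mean RPKM of at least 2.18, the 25th percentile of features detected in both libraries. They were centred on the median of these features. That median was -0.15 in the values as deposited, a ratio of 0.903. A feature was called higher or lower at a 2-fold difference. With 1 library per condition the differences have no replicate check, and no test across genes was run and no p-value is given. Exact (Clopper-Pearson) 95% intervals from the recovered reads are given for ratios and shares. The interval of a list median is the middle 95% of medians from 1000 Poisson resamples of the recovered reads. Both kinds of interval cover counting error only. Because the planned design gave intervals to counts only, they were added after the unit of the values was known.

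Of 35 gene lists fixed in advance, 25 had at least 5 members past the abundance minimum. For these the percentile of the list's median among 10000 random lists of the same size, matched on mean expression in 20 bins, describes how far the list stood apart in this pair of libraries. Runs of at least 4 consecutive features past the minimum, all at least 2-fold in one direction, were counted in file order and set beside 1000 random orders; the planned condition of a shared strand was dropped. Named genes are the 12 highest and the 12 lowest with a symbol, rRNA and tRNA features left out; up to 4 extreme members of each list, or up to 6 where most members lay within 2-fold; the 10 most abundant genes of each library; and members of the runs. Other genes in the text were chosen after their values were seen. These rules and the gene lists were fixed before the data were examined.

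The calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. They were tested on simulated libraries with 200 changed genes. The simulated depths were recovered exactly, and the recovered reads equalled the true reads for 79.2% of 4581 features and never exceeded them. The 2-fold rule found 50% of genes changed 2-fold, 94% of those changed 3-fold and 100% of those changed 4-fold or 8-fold, 50 genes each, and called 0.216% of 3236 unchanged genes. Simulated reads carried counting error only, with no variation between cultures or library preparations, so these rates do not carry over to the real libraries. Above the 97.5th percentile lay 30 of 30 shifted lists, with most genes raised 2-fold, and 0 of 30 unchanged lists, each of 20 genes. Alternatives covered the scaling, the abundance minimum, the pseudocount, the size threshold, the summary and matching of lists, the run length and the rRNA and tRNA features.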

Results

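The data were 1 RNA-seq library of *P. fluorescens* after 1 h in flowback water and 1 library after 1 h in PBS, the control fluid. The question was how the transcriptome of cells in flowback water differed from that of cells in PBS. The values rest on 5417170 reads for flowback water and 5654229 reads for PBS. Of 6106 features, 4530 were detected in both libraries, 133 in flowback water alone and 143 in PBS alone, and 1300 were listed at 0 in both. The 3397 features past the abundance minimum had a median of 135 reads in flowback water and 158 reads in PBS.

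Among features with a gene symbol, several genes for ribosomal proteins stood highest in flowback water relative to PBS. The gene rplV, for large-subunit protein L22, had 339 RPKM in flowback water and 64.3 RPKM in PBS, a 5.83-fold difference (log2 ratio 2.54, counting interval 2.38 to 2.72). Also near the top were cspA3, a member of the cold-shock protein family (5.52-fold, log2 ratio 2.46, interval 2.24 to 2.71), and frr, the ribosome recycling factor (4.36-fold, log2 ratio 2.12, interval 1.85 to 2.44). The flagellar rod gene flgC stood lowest among genes with a symbol, with 1.95 RPKM in flowback water and 22.9 RPKM in PBS (9.49-fold lower, log2 ratio -3.25, interval -4.45 to -2.52; -2.37 with a pseudocount 10 times larger). Most of the transcriptome lay close together: 3134 of 3397 features, or 92.3%, were within 2-fold.

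At least 2-fold higher in flowback water were 147 features, and at least 2-fold lower were 116. The interval from the recovered reads excluded no change for 142 and 112 of these. Of the 147 higher features, 38 had a gene symbol, 12 were rRNA features, 2 were tRNA features and 95 carried a locus tag alone. Of the 116 lower features, 20 had a symbol, 5 were tRNA features, 1 was another small RNA and 90 carried a locus tag alone. Without centring on the median, in the values as deposited, the counts were 98 higher and 171 lower, so that the higher share of these features was 36.4% in place of 55.9%. The deposited values are scaled by all reads, including rRNA features (11.8% in flowback water, 1.44% in PBS) and other small RNA features (18.4% and 25.0%). How much of the difference from the centred counts comes from these shares was not tested. At least 4-fold higher were 21 features and at least 4-fold lower were 8. Across the features past the minimum, Pearson's r of log2 RPKM between the libraries was 0.966 and Spearman's rho was 0.963; these are correlations across genes, which are not independent replicates.

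**Figure D1:**
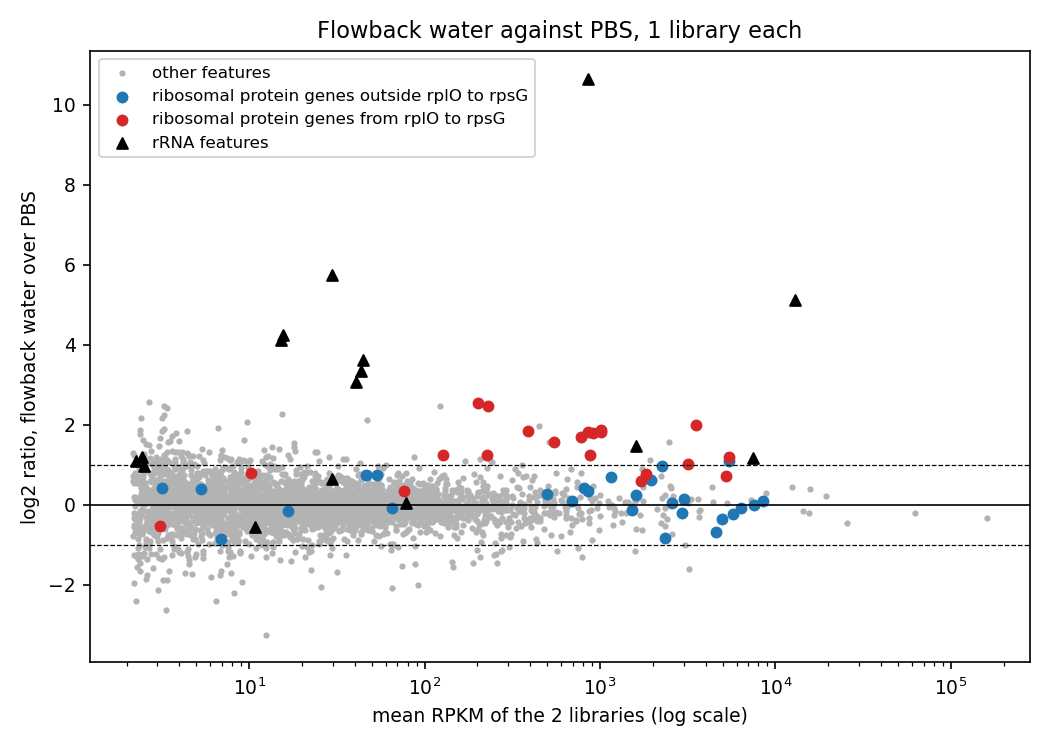
Log2 ratio of flowback water over PBS against the mean RPKM of both libraries (log scale) for the 3397 features past the abundance minimum; each point is 1 feature and dashed lines mark 2-fold. Ribosomal protein genes from rplO to rpsG (red) lie mostly above the 2-fold line, those elsewhere (blue) mostly within 2-fold, and rRNA features (triangles) reach the highest ratios.

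As a list, the ribosomal proteins had a median log2 ratio of 0.60 over 48 measured genes (counting interval 0.51 to 0.68). This lay at percentile 100 of random lists, whose middle 95% ran from -0.10 to 0.15, and at percentile 99.25 of random runs of neighbouring genes. Without the genes from rplO to rpsG the list's median lay within random lists, at percentile 78.7, and without those from rplQ to secE at percentile 44.1. At least 2-fold higher were 16 of the 48, none was 2-fold lower and 32 were within 2-fold. Below 0 were 12 of the 48, the lowest being rplM at -0.86, rpsI at -0.83 and rpmA at -0.68. The highest were rplV, rpsS (5.51-fold, log2 ratio 2.46, interval 2.31 to 2.63), rpsC (4.02-fold, 5540 RPKM against 1526 RPKM, log2 ratio 2.01, interval 1.98 to 2.04) and rpsQ (log2 ratio 1.87). All 52 ribosomal protein genes together took 593788 reads in flowback water and 498130 reads in PBS. In the same libraries the rRNA features took 11.8% of the reads in flowback water and 1.44% in PBS.

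The higher ribosomal protein genes lay close together on the chromosome. In the block of 40 features from rplQ to secE, all of them genes for ribosomal proteins, RNA polymerase, elongation factors, transcript elongation or protein export, 15 of 30 measured ribosomal protein genes were at least 2-fold higher, with a median log2 ratio of 1.00. Outside the block, 1 of 18 was (rpsA, for the largest small-subunit protein, log2 ratio 1.09), and the median was 0.02. All 15 lay from rplO to rpsG, a stretch whose ends were set by these 2-fold calls, so that its contrast with other genes follows in part from that choice; its 21 measured ribosomal protein genes had a median of 1.24. Just outside that stretch rpsL stood at 0.98 and secY at 0.71. In the values as deposited, rpsG (4097 RPKM against 2223 RPKM) and rpsA (7152 RPKM against 3715 RPKM) fell short of 2-fold, so these calls rest on the centring. The block and the genes rpsL, rplW, rplC and rpsJ were chosen after the values were seen. Within the stretch, 10 consecutive genes, rplE, rplX, rplN, rpsQ, rpmC, rplP, rpsC, rplV, rpsS and rplB, formed the only run of at least 4 neighbours that were all 2-fold higher; their median log2 ratio was 1.84 and they ranged from 1.20 to 2.54. At least 1 run of 4 or more higher neighbours, of any length, arose in 3 of 1000 random orders, and there was no run of 2-fold lower neighbours. Random orders also separate neighbours with overlapping spans, whose ratios can move together, so this number does not point to a cause. The run ended at rplW, which lay below the abundance minimum (0.820 RPKM in flowback water and 2.75 RPKM in PBS). Beyond it rplD stood at 1.82, rplC at 0.76, rpsJ at 0.79, tufB, an elongation factor Tu gene, at 0.22 and fusA, the elongation factor G gene, at 1.58 (interval 1.56 to 1.60). The summed reads of all 24 features of the stretch were 458298 in flowback water and 315059 in PBS, a 1.68-fold difference (log2 ratio 0.75, interval 0.74 to 0.76). Taken as a ratio of summed RPKM, the whole ribosomal list stood at 0.39 in place of 0.60.

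**Figure D2:**
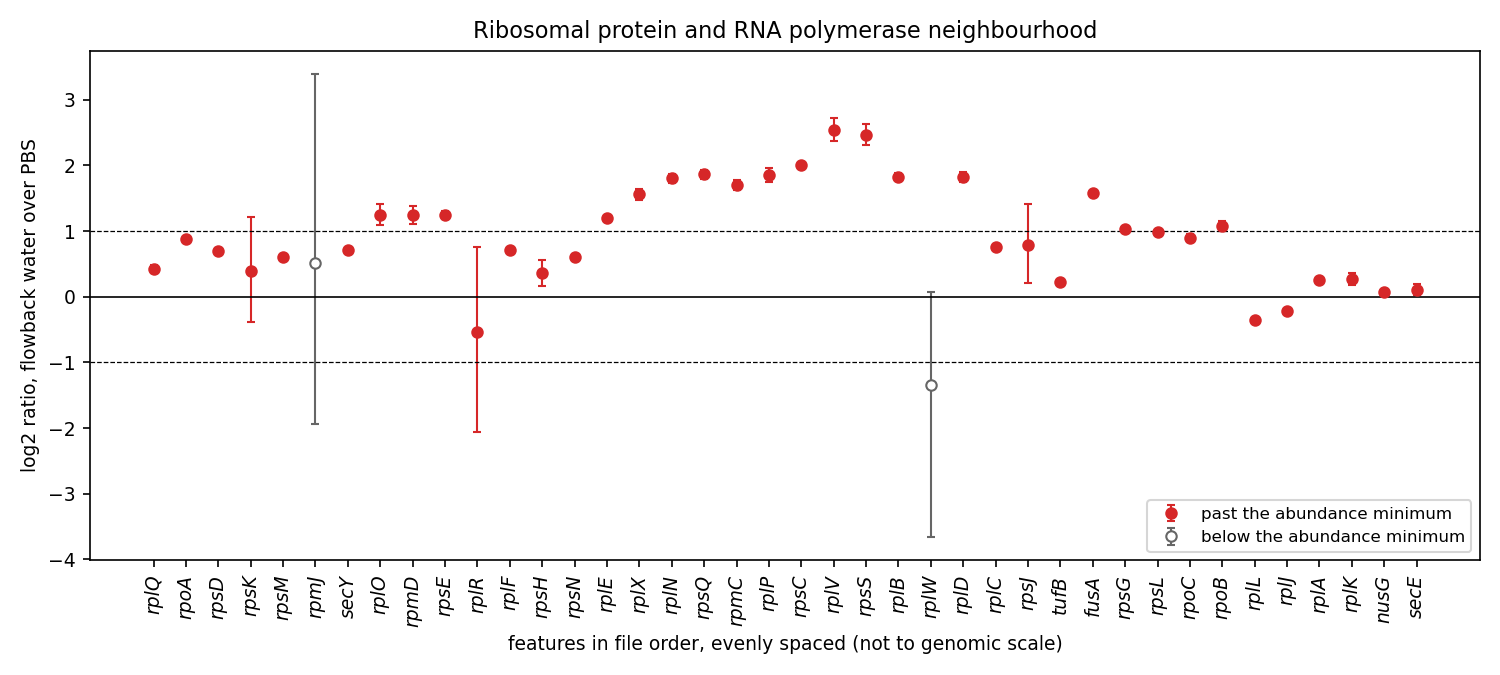
Log2 ratio of flowback water over PBS for the features from rplQ to secE in file order, with exact 95% counting intervals from the recovered reads; open circles mark features below the abundance minimum and dashed lines mark 2-fold. Ratios from rplE to rplB run from 1.20 to 2.54, and those from rplL to secE lie between -0.35 and 0.27.

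Translation factors and RNA polymerase genes had a median log2 ratio of 0.18 over 18 genes, at percentile 96.8 of random lists. The genes frr, fusA and rpoB (log2 ratio 1.08, interval 1.00 to 1.16) were at least 2-fold higher, none was 2-fold lower, and rpoC stood at 0.89 and rpoA at 0.88. In the values as deposited rpoB (318 RPKM against 166 RPKM) fell short of 2-fold. Of the genes named here, fusA lies within the ribosomal stretch, and rpoA, rpoB and rpoC lie next to ribosomal protein genes.

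Genes for fatty acid beta-oxidation and polyhydroxyalkanoate storage were the other list beyond random lists, at a median log2 ratio of 0.58 (percentile 99.7; random lists -0.36 to 0.40). None of the 7 measured members reached 2-fold. The phasin gene phaI, for a storage granule protein, stood at 0.81 (interval 0.61 to 1.01), fadB at 0.63 (0.52 to 0.75), fadA at 0.62 (0.38 to 0.87) and phaC, the polymer synthase, at 0.58 (0.17 to 1.02). The intervals of fadE (0.16) and of both copies of phaG (0.15 and 0.06) included 0, and in the values as deposited a phaG copy was lower in flowback water (20.5 RPKM against 21.7 RPKM). The lists beyond the middle 95% were thus 2 of 25, both above; about 1.25 of 25 would lie beyond it by chance.

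**Figure D3:**
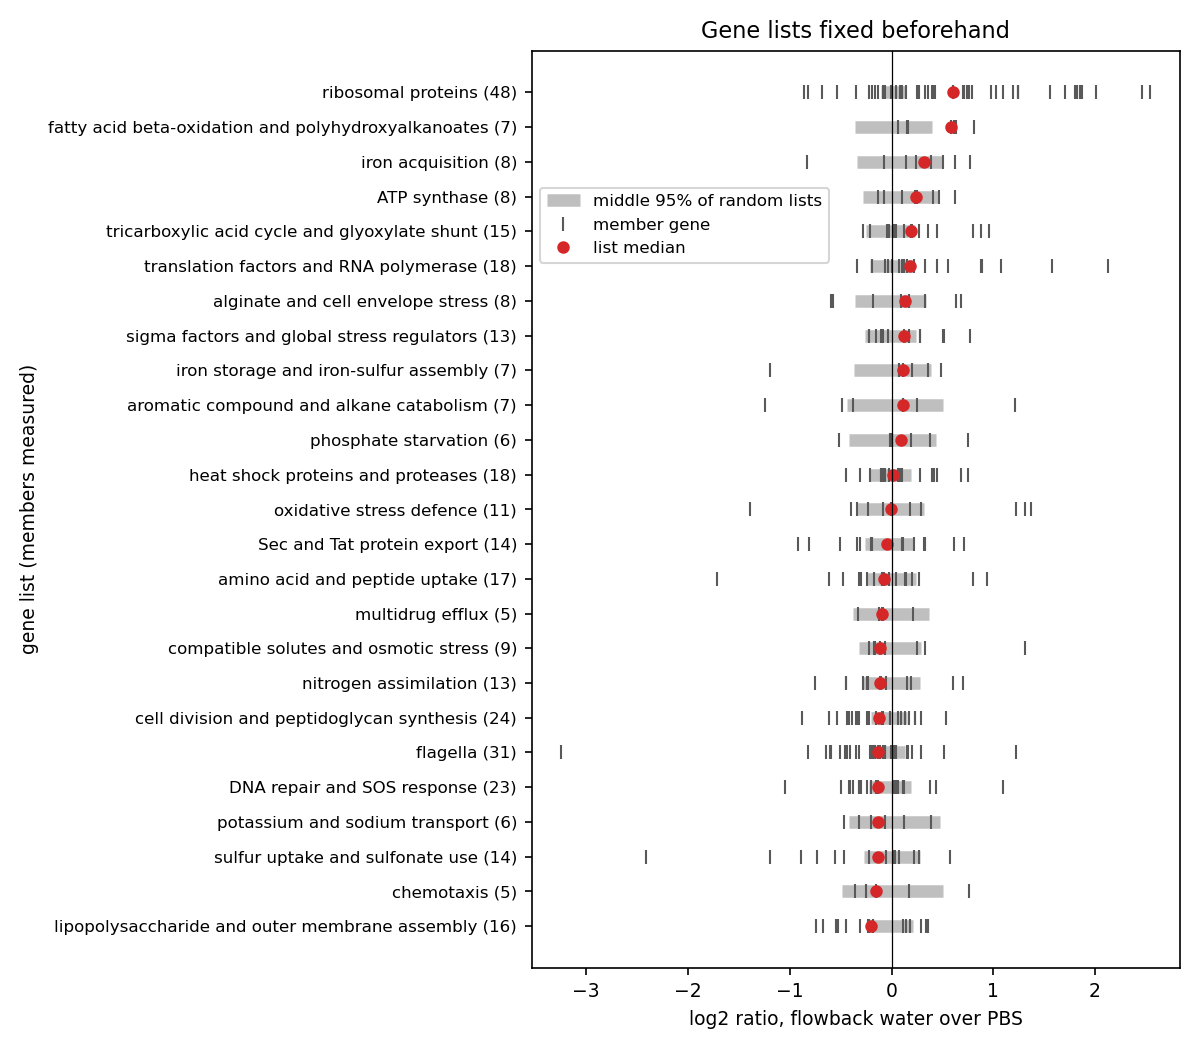
Log2 ratio of flowback water over PBS for the 25 gene lists with at least 5 measured members; ticks are member genes, red points are list medians and grey bars are the middle 95% of 10000 random lists. Only ribosomal proteins (0.60) and fatty acid beta-oxidation with polyhydroxyalkanoates (0.58) have medians outside their grey bars.

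Osmotic stress, ion transport and efflux lists lay within the range of random lists. The compatible solute and osmotic stress list had a median log2 ratio of -0.11 over 9 genes (percentile 30.3). Its osmC, an organic hydroperoxide reductase gene, was the only member past 2-fold, at 1.31 (interval 0.94 to 1.71), while betA stood at 0.33, betI at 0.25 and betT, a choline transporter gene, at -0.22. None of the 6 potassium and sodium transport genes (median -0.13, percentile 21.1) or the 5 multidrug efflux genes (median -0.09, percentile 34.9) reached 2-fold; nhaA, a sodium-proton antiporter gene, stood at -0.47, and acrA at -0.13. Only 4 heavy metal genes were measured, too few for a percentile: cusR stood at 0.93, copA at -0.49, cueR at -0.38 and czcR at -0.15.

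Oxidative stress genes went both ways, with a median of -0.00 over 11 genes (percentile 54.1). The catalase gene katB stood at 1.37 (interval 0.74 to 2.08), soxR, a redox-sensing regulator, at 1.22 (9.49 RPKM against 4.38 RPKM) and osmC at 1.31, whereas ohrR, the regulator of organic hydroperoxide resistance, was 2-fold lower at -1.39 (-1.95 to -0.91). Heat shock proteins and proteases had a median of 0.02 over 18 genes (percentile 61.2) with none past 2-fold; groES stood at 0.75, dnaJ at 0.68, dnaK at 0.45, groEL at 0.42 and htpX at -0.45. Of 23 DNA repair genes (median -0.13, percentile 13.2), mutM was 2-fold higher at 1.10 (0.62 to 1.64) and lexA, the SOS repressor, 2-fold lower at -1.05 (-1.56 to -0.60). With a pseudocount 10 times larger soxR (0.92), mutM (0.89) and lexA (-0.88) lay within 2-fold, and lexA did so with a pseudocount of 1 RPKM (-0.98). Sigma factors and global regulators lay at percentile 86.5 over 13 genes (median 0.12), with pvdS at 0.77, fliA at 0.52, ihfB at 0.51 and rpoS at 0.28.

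The tricarboxylic acid cycle and ATP synthase lists lay within the range of random lists. The tricarboxylic acid cycle list had a median of 0.20 over 15 genes (random lists -0.25 to 0.23), with the succinyl-CoA synthetase genes sucC at 0.88 (interval 0.82 to 0.94) and sucD at 0.80 (0.75 to 0.86), prpD of the methylcitrate cycle at 0.96 (0.41 to 1.62) and sucA at 0.44. The ATP synthase genes had a median of 0.24 over 8 genes (percentile 85.7), from atpG at 0.63 to atpB at -0.13. Of 7 aromatic and alkane catabolism genes (median 0.11, percentile 65.3), pcaH of the protocatechuate pathway was 2-fold higher at 1.21 (0.49 to 2.10), and 0.83 with a pseudocount 10 times larger. The list took in xylA by its symbol, which also names a xylose isomerase gene; the feature lies between xylF and xylR, symbols used for xylose uptake and regulation, and is not read as an aromatic gene. It stood at -1.24 (-2.44 to -0.48) and lay within 2-fold with a pseudocount of 1 RPKM (-0.92) or 10 times larger (-0.59). Its neighbours xylF (1.33) and xylR (2.02), both below the abundance minimum, were higher. Without xylA the list's median was 0.11 (percentile 66.2). Among 3 measured genes of the respiratory list, petA stood at 0.93. The branched-chain amino acid catabolism list had 4 measured members. Of these mmsA, a methylmalonate-semialdehyde dehydrogenase gene, was the only one past 2-fold, at 1.19 in the higher of its copies. Its members phhA (0.22) and hmgA (0.03) are not branched-chain genes.

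Iron acquisition had a median of 0.32 over 8 genes (percentile 89.3) with none past 2-fold; pvdS, the pyoverdine sigma factor, stood at 0.77 (interval 0.41 to 1.16) and fecA at 0.51, against fecB at -0.83 (-1.46 to -0.29). Iron storage and iron-sulfur assembly had a median of 0.11 over 7 genes (percentile 74.7), with cyaY 2-fold lower at -1.19 (-1.96 to -0.55; -0.92 with a pseudocount 10 times larger) and iscS at 0.49. The 6 phosphate genes (median 0.10, percentile 67.7) included phnN at 0.75 and phoR at -0.51, and the 13 nitrogen genes (median -0.11, percentile 22.4) included glnK at 0.60 and ureA at -0.75, none past 2-fold. Among 17 amino acid and peptide uptake genes (median -0.08, percentile 29.9), aotP was 2-fold lower at -1.71 (-2.68 to -0.98), while gltK stood at 0.94 and gltJ at 0.80. The features adjoining aotP, PFLU1306 and PFLU1308, stood at 1.93 and 0.29.

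Sulfur genes included low values in flowback water. Of 14 measured genes for sulfur uptake and sulfonate use (median -0.14, percentile 17.1), ssuE, for a sulfonate-use flavin reductase, was 5.32-fold lower (log2 ratio -2.41, interval -3.64 to -1.66; 11 reads against 76; log2 ratio -1.57 with a pseudocount 10 times larger) and tauA, for taurine binding, was 2-fold lower at -1.19 (-1.82 to -0.68; -0.88 with a pseudocount 10 times larger). The copies of sbp, the sulfate-binding protein gene, stood at -0.89 and -0.73, and cysN at 0.58. Features adjoining ssuE were higher: ssuA at 1.18, below the abundance minimum, and PFLU5859 at 0.59. The gene ssuD stood at 0.02 and tauD at 0.07.

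Envelope and motility lists lay within the range of random lists. Lipopolysaccharide and outer membrane assembly had a median of -0.20 over 16 genes (percentile 3.28) with none past 2-fold; kdsD stood at -0.74 (interval -0.94 to -0.56), lolA at -0.67, lolD at -0.55 and the lipoprotein gene oprI at -0.53 (-0.57 to -0.49). Cell division and peptidoglycan synthesis had a median of -0.13 over 24 genes (percentile 14.3), with pbpG at -0.87 and mreB, for the rod-shape cytoskeleton, at -0.62 (-0.68 to -0.55). Flagella had a median of -0.13 over 31 genes (percentile 8.32), with 22 below 0; flgC was 2-fold lower, flgL 2-fold higher at 1.22 (0.67 to 1.95; 0.81 with a pseudocount 10 times larger), and fliR stood at -0.83. The chemotaxis (median -0.15 over 5, percentile 22.9), alginate and envelope stress (0.13 over 8, percentile 80.4) and Sec and Tat export lists (-0.04 over 14, percentile 40.0) had none past 2-fold. All 5 measured members of the chemotaxis list were wsp genes (wspA, wspC, wspE, wspF and wspR). No feature with a che symbol was measured, so the list does not describe chemotaxis genes at large. In the values as deposited the medians of the heat shock, iron storage, alginate, sigma factor, aromatic and phosphate lists were below 0. The osmotic, oxidative stress, chemotaxis and aromatic lists had means of the opposite sign to their medians (0.12, 0.17, 0.03 and -0.06). Ratios of summed RPKM also opposed the medians of the oxidative stress (0.17), chemotaxis (0.04) and aromatic lists (-0.31). They did so for iron acquisition (-0.03), Sec and Tat export (0.21) and nitrogen (0.03). The Sec and Tat median was 0.13 with the higher minimum, and the heat shock and phosphate medians were -0.003 and -0.03 with no minimum. Of the 10 lists with too few members, those for phage and bacteriocins, antibiotic synthesis and transposases matched no symbol.

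Other named genes that were higher included ispF, for an isoprenoid synthesis enzyme (4.83-fold, log2 ratio 2.27, interval 1.77 to 2.90). Other named genes that were lower included queA, for a tRNA-modifying enzyme, with 1465 RPKM in flowback water and 4971 RPKM in PBS (3.06-fold lower, log2 ratio -1.62, interval -1.64 to -1.59); the adjoining tRNA feature PFLUt74 stood at -1.46. The genes fabG at 744158 to 746102 (-1.76, interval -3.17 to -1.02, and -0.84 with a pseudocount 10 times larger), fabG at 5124075 to 5125422 (-1.34, -2.90 to -0.37), cobH (-1.32), apaG (-1.28) and argD at 1781461 to 1783231 (-1.23) completed the lowest 12. Their recovered reads, which are lower bounds, were 84 or fewer in either library. With a pseudocount 10 times larger cobH (-0.69), argD (-0.82) and the fabG at 5124075 (-0.61) lay within 2-fold, this fabG also with a pseudocount of 1 RPKM (-0.98). The flagellar gene flgC had 11 reads in flowback water and 135 in PBS, while its neighbours flgD and flgB stood at -0.17 each; flgD and flgB were chosen after their values were seen.

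The most abundant genes were nearly the same in both libraries: 9 of the 10 most abundant were shared. The elongation factor gene tufB had 20034 RPKM in flowback water and 19021 RPKM in PBS, the cold-shock gene capB 17105 and 14375, the initiation factor gene infC 13773 and 11182, and the acyl carrier protein gene acpP 9290 and 8333. The gene rplE was among the 10 in flowback water alone, with 7370 RPKM against 3555 in PBS. The 10 most abundant features of all kinds held 42.0% of the reads in flowback water and 40.6% in PBS; without rRNA and tRNA features the order turned, with 38.2% in flowback water and 41.5% in PBS. Small RNA features other than rRNA and tRNA held 18.4% in flowback water (exact interval 18.3 to 18.4) and 25.0% in PBS (25.0 to 25.1), and tRNA features held 1.22% and 1.36%.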

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

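The test of rRNA removal against rRNA synthesis given here was chosen after the result was seen. Ribosomal RNA was not the target of a library made after rRNA removal, yet rRNA features held 11.8% of the reads in flowback water (exact interval 11.8 to 11.9) against 1.44% in PBS (1.43 to 1.45), a signal outside the measured mRNA that lay above its level in the control. The feature PFLUr10, of the size of 23S rRNA, held 8.78% of the reads in flowback water and 0.282% in PBS, and PFLUr18, of the same size, had 32170 reads against 18. Features of 1 size can be near-identical copies, so the split of reads between them is uncertain and only sums per size were weighed. The 5 features of 23S size together were 36.7-fold higher (log2 ratio 5.20, counting interval 5.18 to 5.22). The 3 recovered at 16S size were 2.26-fold higher (1.18, interval 1.16 to 1.19) and the 6 of 5S size were 2.93-fold higher (1.55, interval 1.40 to 1.70). Spans of 5S size were recovered at 720 bases, 120 without flanks, so most of each span is flank and can hold reads of neighbours. Single features of 5S size ran from -0.56 (PFLUr22) and 0.04 (PFLUr6) to 3.63 (PFLUr11), so their sum does not measure 5S rRNA alone. PFLUr12 (recovered span 1069 bases, log2 ratio 1.47) and PFLUr26 (710 bases, 1.20) were left out of these sums. Recovered spans are the smallest that explain the values, so both could be 16S copies with spans and reads recovered too small. The rRNA shares, like the reads, are lower bounds.

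Since 16S and 23S rRNA are cut from one transcript, greater synthesis of rRNA in the exposed cells was predicted to move both by similar factors. Their log2 ratios differed by 4.02. The reads are what rRNA removal left, and removal need not leave the same share of both sizes. The gap therefore does not decide on synthesis. Uneven removal of rRNA between the libraries stays open: it can come with or without such a gap, so no value here decides it. Greater rRNA synthesis stays open as well. Leaving out the rRNA and tRNA features and centring again on the remaining features changed the counts of 2-fold features from 147 and 116 to 133 higher and 110 lower.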

How the results depend on the processing

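The ratio of summed RPKM, the lists without the genes from rplO to rpsG or from rplQ to secE, the aromatic list without xyl genes, the minimum of recovered reads, the counting interval, the lists matched on span and the omission of rRNA and tRNA features from the 2-fold counts were chosen after the data were seen. Counts of 2-fold features moved with thresholds by construction: 369 higher and 302 lower with no abundance minimum, 66 and 43 with the higher minimum of 9.62 RPKM, 67 and 52 with a pseudocount 10 times larger and 21 and 8 at 4-fold. Other scalings, a pseudocount of 1 RPKM and at least 50 recovered reads gave 98 to 147 higher and 86 to 171 lower. The ribosomal list's median was 0.46 in the values as deposited, which are not centred, 0.73 with the higher minimum, 0.39 as a ratio of summed RPKM, 0.10 without the genes from rplO to rpsG and 0.022 without those from rplQ to secE; with no minimum 1 member, rplW, was 2-fold lower. With means in place of medians 4 lists lay beyond random lists, flagella and sulfur uptake being added on the low side (the cause was not tested); 3 did with no minimum (sulfur uptake added) and with at least 50 recovered reads (translation factors added). Runs of at least 3 neighbours numbered 2 higher and 2 lower. Pearson's r was 0.971 with no minimum. Without rRNA and tRNA features the 10 most abundant features held 38.2% in flowback water and 41.5% in PBS. The beta-oxidation list's median ran from 0.44 to 0.64, and its mean was 0.43. Ratios of genes named by the rule or 2-fold in a list were recomputed with scaling by the total or a trimmed mean and with both larger pseudocounts. Of these 168 ratios, none changed sign, 153 stayed at least 2-fold and 15 did not, all with a larger pseudocount. Counting intervals were left by 5 of them (flgC, ssuE, fabG at 744158 and rpsA). The values as deposited were not among these settings, and there rpsA, rpsG, rpoB and mutM fell short of 2-fold. Of 248 medians of other lists 36 moved. List membership by product text could not be run. No paired analysis was possible because each group has 1 library and no test was made. Depth limits the low genes: the abundance minimum is about 31.8 reads over both libraries for a feature of median span.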

Other observations

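The tests of reads moved between neighbours and of stretches that the cells lack were chosen after the result was seen, and the random lists matched on span were added after the data were seen. The cold-shock protein family did not move as a block, cspA1, cspA2 and cspC being chosen after their values were seen. Beside cspA3 at 2.46, cspA1 stood at 1.14 (interval 0.65 to 1.66), with 22.8 RPKM in flowback water and 11.4 RPKM in PBS, and the far more abundant capB at 0.40. On the other side cspA2 stood at -0.29 (3089 RPKM against 4195 RPKM, interval -0.33 to -0.26) and cspC at -0.75 (interval -1.08 to -0.43). The features on either side of cspA3 stood at 0.07 and 0.17.

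Other genes outside the lists were 2-fold lower, and those of this paragraph apart from cobH, ohrR and frr were also chosen after their values were seen. Inorganic pyrophosphatase, ppa at 5981252 to 5982380, had 327 RPKM in flowback water and 815 RPKM in PBS (log2 ratio -1.17, interval -1.24 to -1.09). The ferredoxin gene fdxA stood at -1.13 (161 RPKM against 390 RPKM) and rpiA, for ribose 5-phosphate isomerase, at -1.14 (interval -1.36 to -0.94). The gene cobH at -1.32 lies next to cobI at 1.30, whereas ohrR at -1.39 and its neighbour ohrB at -0.57 were both lower. The uridylate kinase gene pyrH stood at 0.996, just short of 2-fold, next to frr at 2.12.

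The 2-fold higher ribosomal protein genes other than rpsA lay from rplO to rpsG, a stretch bounded by those calls, and 3 explanations were weighed. Reads moved between overlapping neighbours would leave the stretch's summed reads near the median gene, but their log2 ratio was 0.75 (interval 0.74 to 0.76), and 0.59 (0.59 to 0.60) for the block from rplQ to secE, whose ends are set by gene content, which argues against it as the whole cause; it could still shape single genes. A shift of short features as a class is also argued against, since the list's median lay at percentile 100 of random lists matched on mean expression and span. Whether the difference belongs to the treatment or to this pair of libraries cannot be told apart with 1 library per condition. A higher level of these transcripts in flowback water, or a lower one in PBS, thus remains a hypothesis.

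The 1300 features listed at 0 in both libraries lay in long runs along the chromosome. The longest held 62 features, 12 runs held 20 or more, and 67.9% of the features lay in runs of at least 5, against at most 2.77% in 1000 random orders. Low expression at this depth was predicted to give the weakest detected features runs of similar length. The longest run of the 1300 lowest features above 0 was 13. Features at 0 lying among them would break such runs, and the 1300 reach a mean of 1.87 RPKM. The comparison therefore cannot decide on low expression. Stretches of the authors' reference that the cultured strain lacks stay open, since the share in runs describes the pattern itself and does not test them. Among the 40 named features at 0 were 7 of 10 wss genes, for cellulose synthesis, and 6 of 11 rsp genes, for type III secretion. The other wss and rsp genes had low values above 0 in at least 1 library, the highest being rspL (2.88 RPKM in flowback water and 0.768 RPKM in PBS). Silent islands that the strain does carry stay open as well.

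Of 52 ribosomal protein genes, 10 had under 20 RPKM in both libraries, among them rpmB (0.443 RPKM in flowback water and 0.424 RPKM in PBS), rpsR (1.33 and 0.638) and rplM (4.48 and 9.28). All 10 lay next to a feature of at least 500 RPKM, and their median recovered span was 867 bases against 957 for the others. How many of the others lay next to such a feature was not counted. The gene rplV, not among the 10, did so beside rpsC, so such a neighbour is not particular to the low genes.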
